A study of Homo sapiens with 6 samples.

How the data were processed

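RNA was sequenced from HGC-27 cells that carried lentiviral SERPINA4 or GFP, with 3 libraries of each, and poly(A) RNA as the stated molecule. Groups and replicate numbers came from the sample titles. Per the submitters' processing notes, the tools were FastQC, HISAT2 and StringTie and the genome build was GRCh38, and their versions, the annotation and the use of strand in counting are not given in the sources used here. Per the labels' protocols, libraries were made from total RNA extracted with TRIzol.

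The deposited count matrix held estimated counts for 60612 genes, of which 33672 had a count above 0 in any library. The deposited values were already whole numbers, so no rounding was needed. Of 144 values with an FPKM above 0 and under 0.0001, 143 had a count of exactly 1, as a count rounded up would, which can add up to 1 count to genes near the floor. The deposited FPKM table held 33669 genes, and its counts equalled the count matrix for all of them. The 3 other genes held 7 counts. FPKM were computed by the submitters and used here as an alternative unit.

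Total counts per library ran from 47259367 to 72493216, and 3 counts, the limit that a count of 0 allows, were 0.0414 to 0.0635 CPM, counting error only. No pair of libraries held identical values. The chi-square per degree of freedom between pairs was at least 42.5 over genes with a summed count of at least 40, so all pairs differed by more than sampling noise, and pairs with SERPINA4 replicate 2 gave 138 to 163.

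Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 21059. Counts were normalised by TMM, with factors from 0.968 to 1.017, and tested with edgeR's quasi-likelihood F test with robust estimation, 3 SERPINA4 against 3 GFP libraries and no covariate. P-values were two-sided and adjusted by Benjamini-Hochberg. SEs were taken as the absolute log2 fold change over the square root of F. The biological coefficient of variation was 0.335. Levels are CPM with TMM factors, as mean ± SD, except for RNA classes, which are CPM of the total count. The 33 gene lists (833 members, all matched by symbol, 788 in the FPKM table and 45 in the count matrix alone) were tested with camera on voom values at a correlation of 0.01, over lists with at least 5 tested members, and again with an estimated correlation and with fry.

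Named genes followed a rule set before the data were examined: SERPINA4, up to 10 genes with the largest rise and 10 with the largest fall among those past the test (gene symbol, not a clone name, at least 5 CPM in the higher group, groups not overlapping), and for each list up to 3 members past the test or otherwise the member with the lowest p, where the list is discussed beyond its counts. PDIA3, P4HB, PDIA4, UQCRFS1, MT-CO1, NQO1, EGR1, DUSP1, SCD, AXIN2, VEGFA, VIM, CCDC142 and the non-polyadenylated RNAs were chosen after their values were seen.

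The alternatives tried were DESeq2 size factors, upper-quartile factors, library size alone, leaving SERPINA4 out of the scaling, no low-count filter, a filter of 10 CPM in 3 libraries, DESeq2's Wald test, limma-voom, edgeR's test against a log2 fold change of 1, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, and leaving out each library. A fit without robust estimation, and an estimated correlation with the replicate block, were added after the data were seen. Trends over mean expression, exonic length and transcript GC content (GENCODE v29) were removed per library by loess with a span of 0.3.

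The code was tested on simulated counts with the means, dispersions and library sizes of this comparison (20079 genes in the fit). Of genes changed 1.5-fold, 29.9% of 67 were called, of those changed 2-fold 74.6% of 67, and of those changed 4-fold 97% of 66. Of 149 genes called, 15 were unchanged, above the nominal rate. A list shifted by 0.2 on the log2 scale was called and no other list was. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used. The sequence of GFP was not analysed here.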

Results

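Gene expression was measured by RNA sequencing in HGC-27, an established line of human gastric carcinoma cells, after stable lentiviral transduction with SERPINA4 or with green fluorescent protein (GFP) as the control. SERPINA4 encodes kallistatin, a secreted serine proteinase inhibitor that binds tissue kallikrein. There were 3 libraries of SERPINA4 cells and 3 of GFP cells. Total counts were 57618410, 47259367 and 50070976 in GFP replicates 1 to 3 and 67358704, 61766706 and 72493216 in SERPINA4 replicates 1 to 3. Mitochondrial genes took 9.12% ± 0.192 of the counts in GFP and 9.55% ± 0.350 in SERPINA4 libraries (SD, n = 3 each). The labels describe a pair of lines, so the construct and any other difference between the lines go together. No label says that the libraries of a group came from separate cultures, and p-values then measure the spread between these samples, which may be technical.

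The first question was whether the transgene was expressed as the labels state. SERPINA4 (ENSG00000100665, GRCh38 chromosome 14, 94561442 to 94569913, plus strand) had 0, 8 and 16 counts in the GFP libraries and 39960, 36091 and 37919 counts in the SERPINA4 libraries. These were 0.161 ± 0.158 CPM in GFP and 575 ± 36.5 CPM in SERPINA4 (SD, n = 3 each). A count of 0 in GFP replicate 1 allows up to 0.0514 CPM, counting error only. The pooled counts differed 3749-fold, and the fitted log2 fold change was 11.85 with an SE of 0.57 (adjusted p = 0.0299, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). SERPINA4 ranked 188 by mean CPM in the SERPINA4 libraries and took 0.0565% of their counts. Its adjusted p missed 0.05 by limma-voom (0.172, log2 fold change 12.96) and with no low-count filter (0.0584). It also did so without GFP replicate 2 (0.225), GFP replicate 3 (0.0899) or SERPINA4 replicate 1 (0.0831), 2 (0.0638) or 3 (0.122). With 1 library left out, the log2 fold change was 11.20 to 12.85.

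The second question was which other genes differed with SERPINA4 overexpression. Besides SERPINA4, 1 gene rose and 7 fell. NFAT5, the transcription factor of the response to hypertonic stress, fell from 53.6 ± 4.03 to 18.4 ± 2.21 CPM. ADD3, the gamma subunit of the membrane skeleton protein adducin, fell from 89.6 ± 4.39 to 41.6 ± 5.64 CPM, and MXI1, a MAX-binding repressor that opposes MYC, fell from 51.0 ± 2.11 to 26.7 ± 3.35 CPM. CDC25B, the phosphatase that activates cyclin-dependent kinases at entry into mitosis, fell from 100.2 ± 0.426 to 66.5 ± 4.30 CPM. Among zinc-finger genes, ZNF302 fell from 51.6 ± 0.805 to 21.7 ± 3.00 CPM and ZNF532 fell from 65.7 ± 2.48 to 38.4 ± 0.388 CPM, while ZNF652 rose from 53.4 ± 4.67 to 89.6 ± 3.17 CPM (SD, n = 3 each). MRPL53, which encodes a protein of the large mitochondrial ribosomal subunit, fell from 15.4 ± 2.57 to 4.05 ± 0.359 CPM. In each of these genes the 3 SERPINA4 libraries lay outside the range of the 3 GFP libraries.

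**Figure D1:**
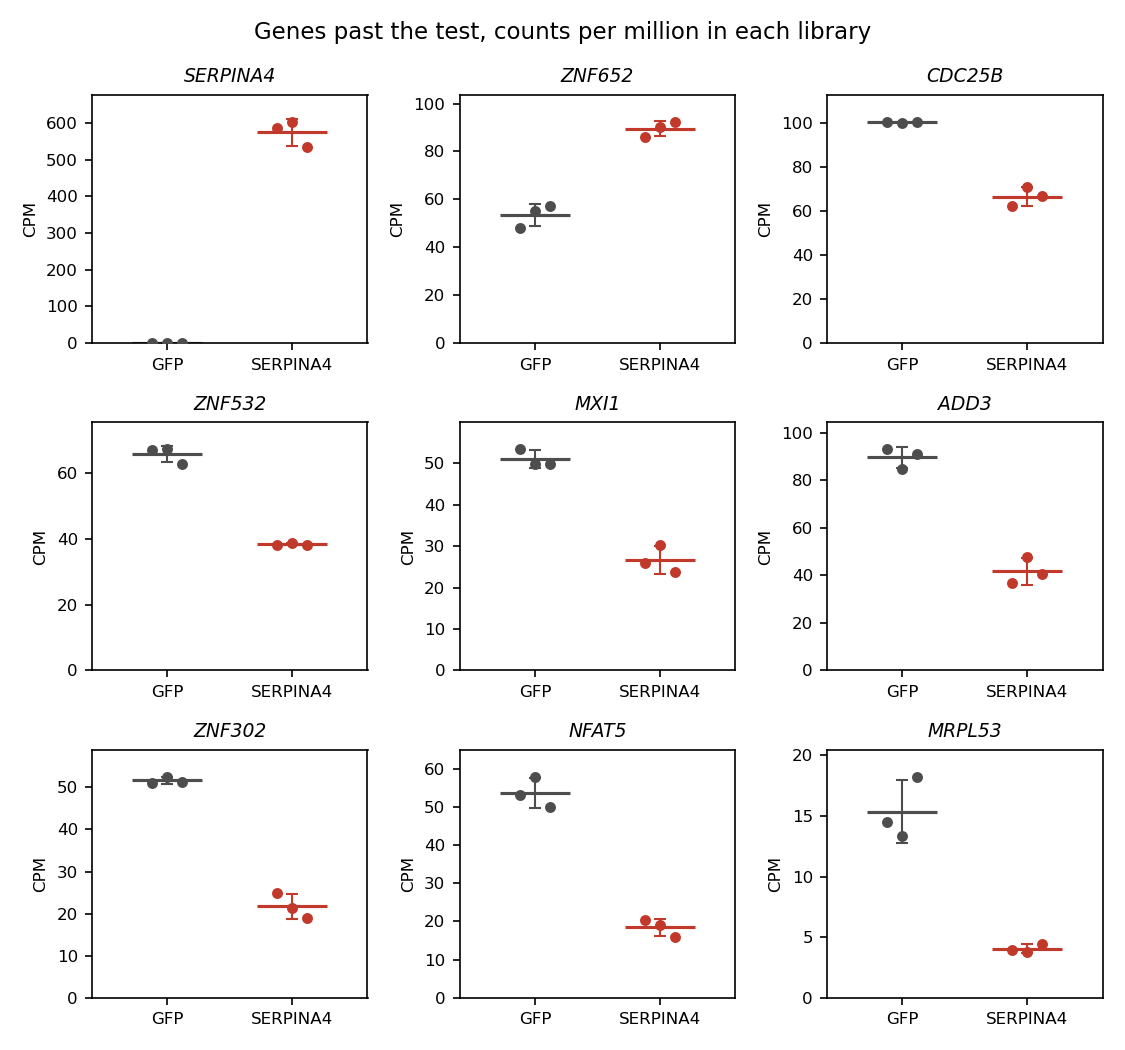
CPM (y axes, each starting at 0) of the 9 genes past the test in the 3 GFP and 3 SERPINA4 libraries, where points are libraries, long bars are means and error bars are SD. The groups did not overlap for any of the 9 genes, and SERPINA4 and ZNF652 were the genes that rose.

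The log2 fold changes were −1.54 (SE 0.11, adjusted p = 0.0109) for NFAT5, −1.11 (SE 0.10, adjusted p = 0.0135) for ADD3, −0.94 (SE 0.10, adjusted p = 0.0325) for MXI1 and −0.59 (SE 0.064, adjusted p = 0.0299) for CDC25B in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. They were −1.25 (SE 0.11, adjusted p = 0.0135) for ZNF302, −0.78 (SE 0.066, adjusted p = 0.0135) for ZNF532, 0.75 (SE 0.078, adjusted p = 0.0299) for ZNF652 and −1.92 (SE 0.17, adjusted p = 0.0135) for MRPL53 in the same edgeR fit. NFAT5 (ENSG00000102908) lies on chromosome 16, 69565094 to 69704666, ZNF652 (ENSG00000198740) on chromosome 17, 49289206 to 49362473, ZNF302 (ENSG00000089335) on chromosome 19, 34677639 to 34686396, ZNF532 (ENSG00000074657) on chromosome 18, 58862600 to 58986480, and CDC25B (ENSG00000101224) on chromosome 20, 3786772 to 3806121. ADD3 (ENSG00000148700, 109996368 to 110135565) and MXI1 (ENSG00000119950, 110207605 to 110287365) are neighbours on chromosome 10, on the same strand and 72040 bases apart. MRPL53 (ENSG00000204822) on chromosome 2, 74471982 to 74472687, lies almost wholly inside the span of CCDC142 on the same strand.

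Of 21059 genes tested, 9 passed an adjusted p of 0.05, and 1156 (5.49%) had an unadjusted p under 0.05, 615 higher and 541 lower. The groups did not overlap in 13% of tested genes, against 10% by chance for 3 against 3. The median log2 fold change of all tested genes was 0.00. DESeq2 called 72 genes, the 9 among them. Limma-voom called 8 of the 9, all but SERPINA4. Without robust estimation in edgeR, ZNF652, CDC25B and MXI1 missed the test (adjusted p = 0.0746, 0.0776 and 0.0818), and with genes of at least 10 CPM in 3 libraries alone MXI1 did (0.0536). On log2(FPKM + 0.1) ADD3, CDC25B, MRPL53 and SERPINA4 passed, and on log2(FPKM + 1) MRPL53 and SERPINA4. No gene passed an edgeR test against a log2 fold change of 1, where 67 genes had an unadjusted p under 0.05.

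The edgeR fit with 1 library left out called 15 genes without GFP replicate 1 and 22, 30 and 19 without SERPINA4 replicates 1, 2 and 3. NFAT5, ZNF532 and MRPL53 passed the test with any 1 library left out. ADD3 and ZNF302 missed it without GFP replicate 3 (adjusted p = 0.0601 and 0.0540), ZNF652 without GFP replicate 2 (0.0816), GFP replicate 3 (0.0601) or SERPINA4 replicate 3 (0.0615), CDC25B without any 1 of the GFP replicates (up to 0.131) or SERPINA4 replicate 3 (0.0745), and MXI1 in every such edgeR fit but that without SERPINA4 replicate 2 (up to 0.131).

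MRPL53 and CCDC142 share 608 exonic bases in the GENCODE v29 annotation, and how the counting divided reads between them is not given in the sources used here. CCDC142 had 13.6 ± 3.18 CPM in GFP and 19.4 ± 3.81 CPM in SERPINA4 libraries (SD, n = 3 each), a log2 fold change of 0.51 (SE 0.20, edgeR adjusted p = 0.891). The counts of MRPL53 summed with the genes that overlap it were 29.9 ± 2.71 CPM in GFP and 24.2 ± 3.51 CPM in SERPINA4 libraries, a log2 fold change of −0.30 (SE 0.13, edgeR adjusted p = 0.891). CCDC142 was chosen after its values were seen.

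**Figure D2:**
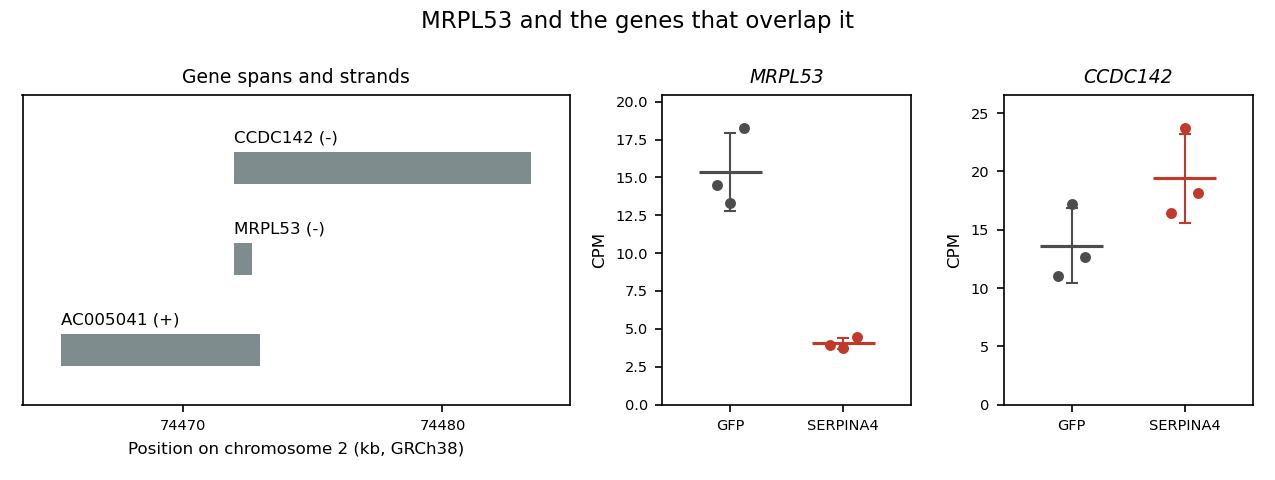
Spans and strands of MRPL53 and the genes that overlap it on chromosome 2 (x axis in kb, GRCh38), and CPM of MRPL53 and CCDC142 (y axes from 0) in the 3 GFP and 3 SERPINA4 libraries, where points are libraries, long bars are means and error bars are SD. MRPL53 was at 15.4 CPM in GFP and 4.05 CPM in SERPINA4 libraries, and CCDC142 at 13.6 and 19.4 CPM.

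The third question was whether the genes of known pathways moved together. Of 33 gene lists fixed before the data were examined, 31 had enough tested members, and 10 differed from the other genes at an adjusted p of 0.05 by camera with its preset correlation, 9 of them higher and 1 lower. None passed with an estimated correlation, where 4 had an unadjusted p under 0.05. By fry, which tests a list against no change and not against other genes, none passed in either direction, and 4 had an unadjusted p under 0.05. Fry's mixed test, which lets members change either way and gives no direction, passed other calls. These were the fatty acid, G2 and M phase, NRF2, epithelial, hypoxia, ER and S phase lists (adjusted p = 1.5e-05 to 0.0436). Of the 716 list members tested, MXI1 fell and no member rose when adjusted over all genes. Adjusted over the list alone, 9 members rose and 1 fell. On log2(FPKM + 1) and on log2(FPKM + 0.1) the lists of ER chaperones, respiratory chain, histones, immediate early genes and fatty acid metabolism passed, and the 5 others did not. With genes of at least 10 CPM in 3 libraries alone, the S phase, NRF2, fatty acid and immediate early lists missed the test (adjusted p = 0.106, 0.0638, 0.0814 and 0.0652) and the histone list had too few tested members.

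Endoplasmic reticulum (ER) chaperones and genes of the unfolded protein response stood higher in the SERPINA4 libraries, with 21 of 25 members above 0 and a median log2 fold change of 0.11 (camera adjusted p = 3.7e-06, and adjusted p = 0.276 with an estimated correlation). Adjusted over the list alone, 4 members rose. HSPA5, the ER chaperone BiP, was at 695 ± 12.04 CPM in GFP and 805 ± 26.9 CPM in SERPINA4 libraries (SD, n = 3 each, log2 fold change 0.21). The protein disulfide isomerases PDIA3, P4HB and PDIA4 had log2 fold changes of 0.18, 0.18 and 0.16. Among collagen and protease inhibitor genes, the collagen chaperone SERPINH1 was at 801 ± 49.8 CPM in GFP and 953 ± 39.1 CPM in SERPINA4 libraries, and it rose when its list of matrix proteases and their inhibitors was adjusted over the list alone. That list did not pass (13 of 24 members above 0, median 0.02, camera adjusted p = 0.0600). It passed without GFP replicate 2 (camera adjusted p = 0.00589), with genes of at least 10 CPM in 3 libraries alone (0.0194) and with the replicate block (0.0314). Its median was 0.093 without GFP replicate 2 and 0.086 without GFP replicate 3.

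The nuclear-encoded respiratory chain had 25 of 28 members above 0 and a median log2 fold change of 0.097 (camera adjusted p = 5.5e-05, and adjusted p = 0.513 with an estimated correlation). COX5A, a subunit of cytochrome c oxidase, was at 78.3 ± 3.48 CPM in GFP and 96.9 ± 1.24 CPM in SERPINA4 libraries and rose when adjusted over the list alone, and the iron-sulfur protein of complex III, UQCRFS1, had a log2 fold change of 0.11. The 13 mitochondrially encoded genes had 9 members above 0 and a median of 0.097 (camera adjusted p = 0.00497, and adjusted p = 0.558 with an estimated correlation). Without SERPINA4 replicate 3 the medians of the mitochondrially encoded and ribosomal protein lists were 0.044 and 0.039. They were 0.057 and 0.021 with library size as the scaling, and 0.048 and 0.013 on log2(FPKM + 1). The median of all tested genes was −0.038 and −0.023 in these settings. MT-CO1 was at 19243 ± 103 CPM in GFP and had a log2 fold change of 0.097, while MT-ATP8, whose gene overlaps MT-ATP6, was at 4589 ± 136 CPM in GFP and 4135 ± 226 CPM in SERPINA4 libraries. Ribosomal proteins had 26 of 30 members above 0 and a median of 0.061 (camera adjusted p = 4.8e-05, and adjusted p = 0.533 with an estimated correlation), with RPL11 at 626 ± 34.8 CPM in GFP and 728 ± 40.9 CPM in SERPINA4 libraries. After the trend over mean expression was removed from each library, the medians of the ribosomal protein and mitochondrially encoded lists were 0.012 and 0.0072.

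Cell cycle lists moved little. The G2 and M phase list had 26 of 30 members above 0 with a median log2 fold change of 0.039 (camera adjusted p = 0.00509, and adjusted p = 0.276 with an estimated correlation), and the S phase list had 19 of 28 above 0 with a median of 0.049 (camera adjusted p = 0.0347, and adjusted p = 0.513 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, was at 104.3 ± 3.13 CPM in GFP and 126 ± 3.51 CPM in SERPINA4 libraries and rose when adjusted over the list alone. MCM7, a subunit of the replicative helicase, had a log2 fold change of 0.15. With library size as the scaling, neither list passed (adjusted p = 0.256 and 0.192) and their medians were 7.9e-05 and 0.0094. The median of all tested genes was −0.038 there. On log2(FPKM + 1) the G2 and M phase median was −0.0078 and the S phase median 0.0017, against −0.023 for all tested genes. The G2 and M phase list missed the test without SERPINA4 replicate 1 (adjusted p = 0.0598), and the S phase list without GFP replicate 3 (0.334, median 0.012), SERPINA4 replicate 2 (0.150, median 0.021) or SERPINA4 replicate 3 (0.104).

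NRF2 and antioxidant genes had 20 of 26 members above 0 and a median log2 fold change of 0.089 (camera adjusted p = 0.00564, and adjusted p = 0.276 with an estimated correlation). The quinone reductase NQO1 had 216 ± 8.66 CPM in GFP and a log2 fold change of 0.39, and the sulfiredoxin SRXN1 one of 0.20, and neither passed the edgeR test over all genes, though NQO1 did so without SERPINA4 replicate 2 (0.50, adjusted p = 0.0379). With library size as the scaling the NRF2 list missed the test (adjusted p = 0.0669), and its median was 0.053 without GFP replicate 1 or 2.

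Immediate early genes had 19 of 27 above 0 and a median of 0.19 (camera adjusted p = 0.0369, and adjusted p = 0.558 with an estimated correlation). FOS was at 330 ± 2.53 CPM in GFP and 607 ± 120 CPM in SERPINA4 libraries and rose when adjusted over the list alone, but missed the test over all genes (edgeR adjusted p = 0.447). FOS passed by DESeq2 (adjusted p = 4.6e-09) and without SERPINA4 replicate 3 (log2 fold change 0.71, edgeR adjusted p = 0.00219). EGR1 had a log2 fold change of 0.64 (adjusted p = 0.00629 by DESeq2) and DUSP1, a phosphatase of MAP kinases, one of 0.36. The immediate early list missed the test with no low-count filter (adjusted p = 0.0776) and without GFP replicate 2 (adjusted p = 0.0897), GFP replicate 3 (0.245), SERPINA4 replicate 2 (0.0593) or SERPINA4 replicate 3 (0.104). Its median was 0.012 without SERPINA4 replicate 3, 0.057 without GFP replicate 2 and 0.11 without GFP replicate 1. The list that stood lower was that of fatty acid synthesis and oxidation, with 19 of 25 members below 0 and a median of −0.063 (camera adjusted p = 0.0122, and adjusted p = 0.276 with an estimated correlation; adjusted p = 0.110 without GFP replicate 3; median −0.10 without SERPINA4 replicate 1). ACSL4, an acyl-CoA synthetase for polyunsaturated fatty acids, was at 129 ± 2.67 CPM in GFP and 91.3 ± 15.3 CPM in SERPINA4 libraries (adjusted p = 0.736 by edgeR, 0.0248 by DESeq2 and 0.0131 by edgeR without SERPINA4 replicate 2), and the stearoyl-CoA desaturase SCD had a log2 fold change of −0.10.

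Replication-dependent histone genes, whose transcripts end without a poly(A) tail, had 21 of 22 members above 0 and a median log2 fold change of 0.92 (camera adjusted p = 0.00469, and adjusted p = 0.624 with an estimated correlation). H2BC4, an H2B gene, was at 0.548 ± 0.319 CPM in GFP and 1.76 ± 0.840 CPM in SERPINA4 libraries. The summed expression of the list was 109.5 CPM in SERPINA4 replicate 2 and 49.0 to 55.1 CPM in the other libraries. Without SERPINA4 replicate 2, 14 of 22 members were above 0, the median was 0.19 and the list did not pass (camera adjusted p = 0.230). The same library held more of other RNAs that lack a poly(A) tail. RN7SL1 and RN7SL2, the RNA of the signal recognition particle, summed to 874 CPM there and to 11.5 to 68.7 CPM in the others, and RN7SK to 168 against 1.29 to 12.4 CPM. A set of 4 long non-coding RNA genes on chromosome 21, of which 3 lie within 45S ribosomal RNA genes, took 3.21% of its counts, against 0.0599% to 0.263% in the others. In each of these classes SERPINA4 replicate 3 came next. These RNAs were chosen after their values were seen.

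**Figure D3:**
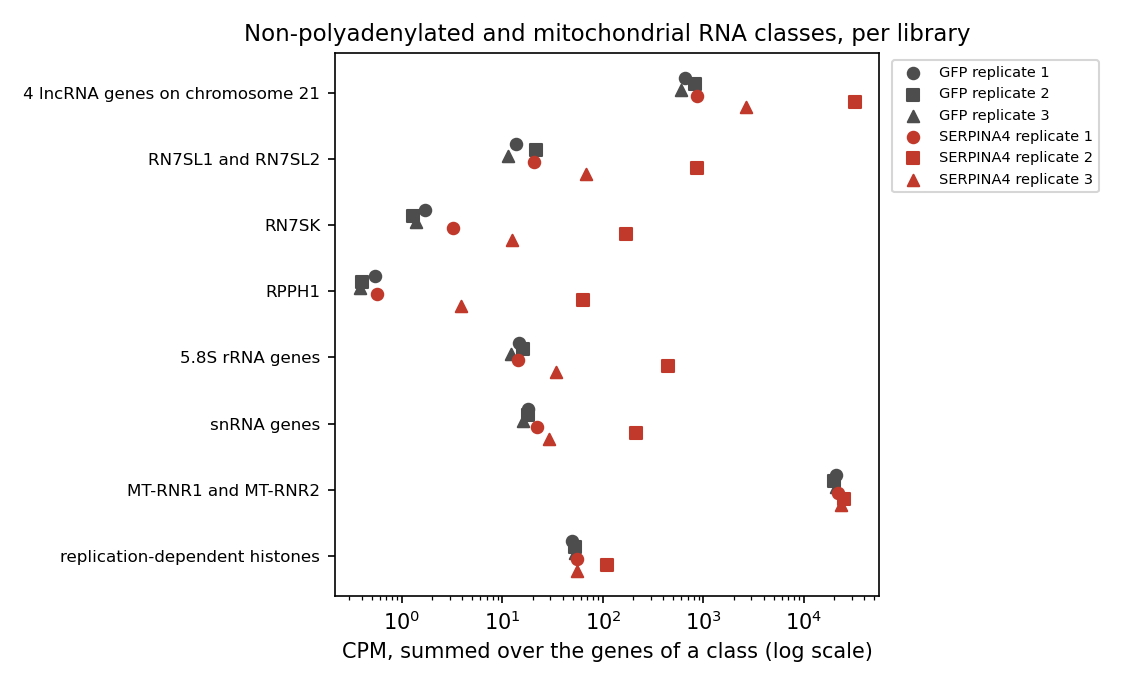
CPM (x axis, log scale) summed over the genes of each of 8 RNA classes (y axis) in each library, with colour for the group and marker shape for the replicate number. SERPINA4 replicate 2 stood apart from the other 5 libraries in all classes but the mitochondrial ribosomal RNAs, with 109.5 CPM of histone transcripts against 49.0 to 55.1 CPM.

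The Wnt/beta-catenin, NF-kB, angiogenic, kallikrein-kinin, mesenchymal and epithelial lists did not pass by camera. Wnt/beta-catenin targets had 11 of 23 members above 0 (median log2 fold change −0.035, camera adjusted p = 0.637), with NKD1, a Wnt feedback inhibitor, at 568 ± 6.36 CPM in GFP and 518 ± 12.5 CPM in SERPINA4 libraries and AXIN2 at a log2 fold change of −0.12. The Wnt median was 0.010 without GFP replicate 2, 0.056 without GFP replicate 3 and 0.016 without SERPINA4 replicate 3. NF-kB targets had 7 of 19 above 0 (median −0.14, camera adjusted p = 0.657), with BIRC3 at 2.32 ± 0.193 and 1.29 ± 0.293 CPM. The NF-kB median was −0.068 without GFP replicate 2 and 0.011 without GFP replicate 3. It was 0.11 over the 5 members tested with genes of at least 10 CPM in 3 libraries alone. Angiogenic and lymphangiogenic factors had 9 of 25 above 0 (median −0.032, mean 0.052, camera adjusted p = 0.637). SEMA3C was at 74.3 ± 1.54 CPM in GFP and 62.5 ± 8.76 CPM in SERPINA4 libraries. VEGFA was at 255 ± 5.04 CPM in GFP and 254 ± 7.59 CPM in SERPINA4 libraries. The kallikrein-kinin system had 6 of 11 above 0 (camera adjusted p = 0.640), and clade A serpins had 2 tested members, with SERPINA1 at 0.701 ± 0.455 and 0.400 ± 0.146 CPM. Mesenchymal markers had 14 of 25 above 0 (camera adjusted p = 0.770), with VIM at a log2 fold change of 0.19 and PRRX1 at one of −0.14. The log2 fold change of VIM was 0.11 to 0.29 with 1 library left out. Epithelial markers had 9 of 17 above 0 (camera adjusted p = 0.609), with EPCAM under 1 CPM in both groups.

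Of the lists on stress and cell death, p53 targets had 13 of 25 members above 0 (camera adjusted p = 0.899), apoptosis regulators 15 of 27 (0.991), ATF4 targets 15 of 28 (0.637), interferon-stimulated genes 19 of 28 (0.237), and hypoxia and glycolysis 18 of 29 (0.188), where MXI1 was the member that fell. Cholesterol synthesis and uptake had 14 of 25 above 0 (camera adjusted p = 0.637), autophagy and lysosome 17 of 28 (0.637), and MYC and ribosome biogenesis 16 of 27 (0.207). YAP/TEAD targets had 14 of 23 above 0 (0.967), with CCN1 at 26.2 ± 2.60 CPM in GFP and 38.6 ± 4.22 CPM in SERPINA4 libraries (SD, n = 3 each), which rose when adjusted over the list alone and by DESeq2 over all genes (adjusted p = 0.0164), and collagens, laminins and integrins had 16 of 29 above 0 (0.967). Markers of other cell types showed no list that passed by camera: gastric epithelium (5 of 8 above 0, adjusted p = 0.805), hepatocytes (5 of 9, 0.412), fibroblasts (8 of 14, 0.637) and immune cells (3 of 12, 0.967), while endothelial markers had 4 tested members, 1 of them above 0. In 8 of the lists that did not pass, the median, the mean and the test differed in sign, as in the hepatocyte list (median 0.12, mean −0.24, tested lower).

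**Figure D4:**
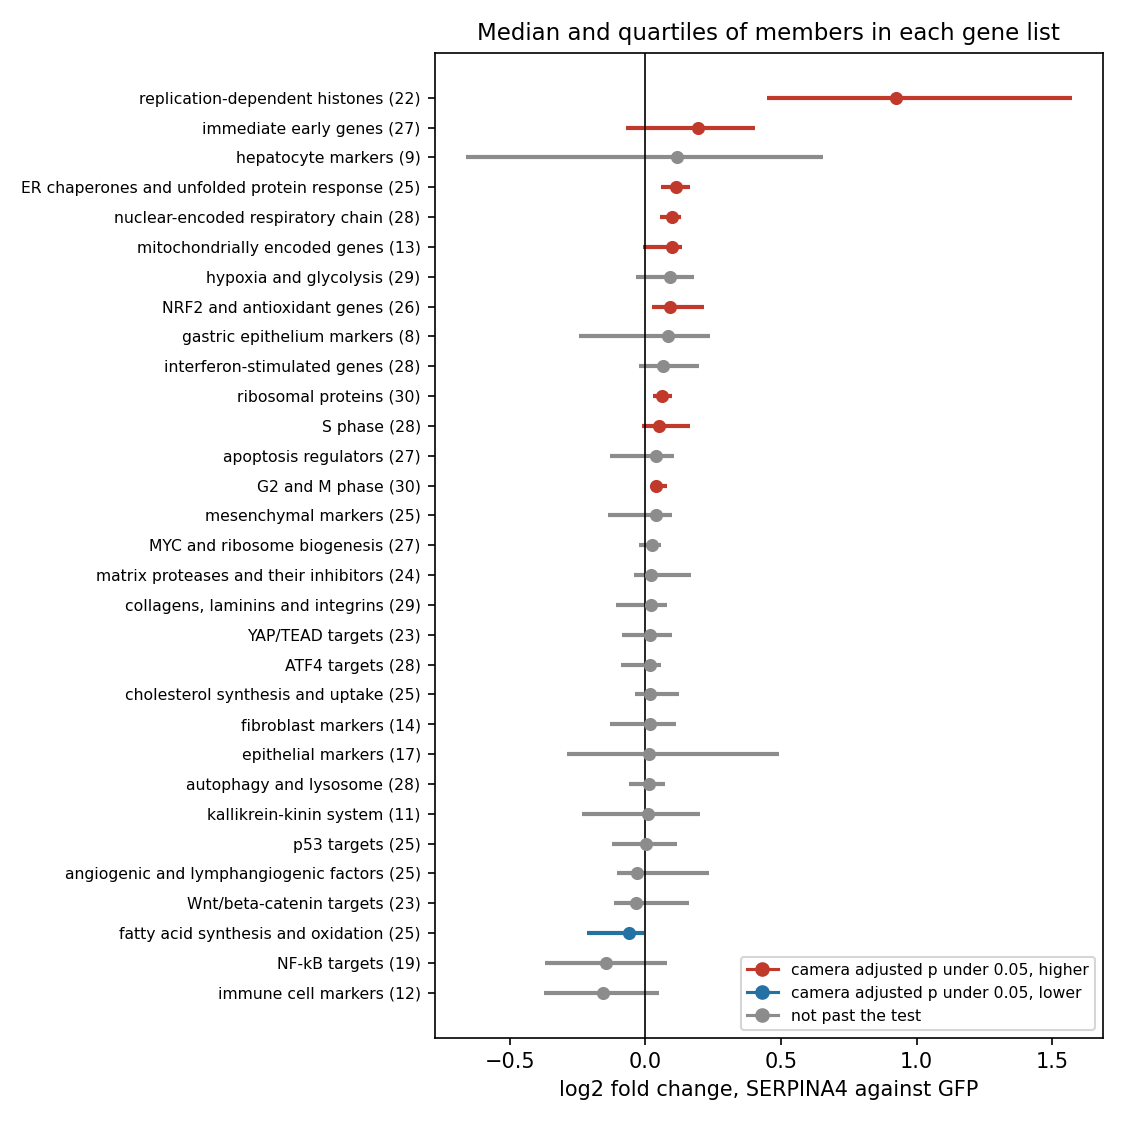
Median (points) and quartiles (lines) of the log2 fold changes (x axis, SERPINA4 against GFP) of the tested members of 31 gene lists (y axis, number tested in parentheses), with colour for a camera adjusted p under 0.05 at the preset correlation. The histone list had the highest median, 0.92, which was 0.19 without SERPINA4 replicate 2, and the ER list had a median of 0.11.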

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

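The fit without robust estimation and the estimated correlation with a replicate block were chosen after the data were seen. The 9 called genes were the same under DESeq2 size factors, upper-quartile factors, library size alone and scaling without SERPINA4. Of the 9, 8 passed with the filter of 10 CPM (not MXI1, adjusted p = 0.0536), 8 by limma-voom (not SERPINA4), 6 without robust estimation (not ZNF652, 0.0746, CDC25B, 0.0776, or MXI1, 0.0818) and 4 on log2(FPKM + 0.1), where 6 genes were called. The number of genes was 18 with no low-count filter (8 of the 9 among them), 72 by DESeq2 (34 up, 38 down, all 9 among them), 3 on log2(FPKM + 1) (2 of the 9) and 0 against a log2 fold change of 1 (edgeR, 67 at an unadjusted p under 0.05, and 72 by DESeq2 against 0), and the cause was not tested. Leaving out 1 library gave 7 to 30 genes: 15, 10 and 7 without GFP replicates 1, 2 and 3, and 22, 30 and 19 without SERPINA4 replicates 1, 2 and 3. The log2 fold change of SERPINA4 was 11.20 to 12.85 with 1 library left out. It missed the adjusted threshold with no filter (11.85, adjusted p = 0.0584), by limma-voom (12.96, adjusted p = 0.172) and against a log2 fold change of 1 (11.85, adjusted p = 0.229), in a range from 1.7e-21 to 0.648 over its alternatives. The cause was not tested.

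The number of lists was 0 with an estimated correlation and 0 in either direction by fry (4 at an unadjusted p under 0.05 in each, 10 by camera at its preset), 6 with the filter of 10 CPM, 5 on log2(FPKM + 1) and 5 on log2(FPKM + 0.1). Leaving out 1 library gave 7 to 10. The ER and respiratory chain lists lost their call with an estimated correlation, with that and the block, and by fry's test of a direction. They kept it under the 17 other alternatives. Their medians were 0.074 and 0.054 with library size alone, and 0.056 and 0.043 on log2(FPKM + 1). In these settings the median of all tested genes was −0.038 and −0.023, so part of the lower medians is a shift of all genes. With library size alone the NRF2 and fatty acid medians were 0.049 and −0.10. On log2(FPKM + 1) the NRF2, immediate early and histone medians were 0.017, 0.035 and 0.34. No called list or called gene changed direction in its test. The G2 and M phase median was −0.0078 on log2(FPKM + 1) and −0.0079 on log2(FPKM + 0.1), against −0.023 and −0.038 for all tested genes. Limma-voom and the test against a log2 fold change of 1 give no list result of their own.

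The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at −0.0082, 0.014 and 0.0096, and not every sample correlated best with its own number. With the replicate block, edgeR called 0 genes (1030 at an unadjusted p under 0.05, 72 by DESeq2 without it), SERPINA4 had a log2 fold change of 11.85 (adjusted p = 0.648), and 11 lists were called at the preset correlation and 0 with the block and an estimated correlation. The block leaves fewer degrees of freedom.

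The following lists, none past the test there or in the main comparison, changed sign. The unadjusted p, by camera except where fry is named, was for apoptosis regulators 0.932 by fry, 0.980 with upper-quartile factors, 0.877 with no filter, 0.908 on log2(FPKM + 1) and 0.890 on log2(FPKM + 0.1); for immune cells 0.963 by fry, 0.794 with library size alone, 0.626 with no filter and 0.925 by DESeq2; for mesenchymal markers 0.988 with library size alone, 0.999 on log2(FPKM + 1) and 0.958 on log2(FPKM + 0.1); for cholesterol synthesis 0.971, 0.801 and 0.794 and for collagens 0.587, 0.756 and 0.770 in the same 3 settings; for autophagy 0.918 on log2(FPKM + 1) and 0.894 on log2(FPKM + 0.1); for YAP/TEAD targets 0.960 with library size alone and 0.969 with no filter; for the kallikrein-kinin system 0.453 with no filter and 0.664 by DESeq2; for gastric epithelium 0.744 with no filter and 0.898 by DESeq2; for hepatocytes 0.536 by DESeq2; for NF-kB targets 0.323 with the filter of 10 CPM; and for p53 targets 0.956 with that filter and 0.992 on log2(FPKM + 0.1). With 1 library left out, p ran from 0.477 to 0.982 for p53 targets, 0.356 to 0.917 for gastric epithelium, 0.553 to 0.992 for apoptosis regulators, 0.160 to 0.787 for fibroblasts, 0.263 to 0.921 for immune cells, 0.677 to 0.999 for YAP/TEAD targets, 0.0718 to 0.897 for hepatocytes and 0.268 to 0.879 for mesenchymal markers. The log2 fold change of VEGFA was 0.0041 with upper-quartile factors, 0.0018 with no filter and −0.021 to 0.019 with 1 library left out. The cause was not tested.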

Other observations

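Among 3669 Gene Ontology terms of 10 to 500 tested genes, chosen as a test after the data were seen, camera at the preset correlation called 36 higher and 2 lower in SERPINA4 libraries, 29 of them also without SERPINA4 replicate 2, and 0 with an estimated correlation (smallest adjusted p = 0.977, 56 at an unadjusted p under 0.05). Besides ribosome and respiratory chain terms, protein disulfide isomerase activity had 16 of 18 members above 0 (adjusted p = 0.000652), and the U2-type precatalytic spliceosome had 38 of 50 (adjusted p = 0.00236). The tubulin gene TUBA1A was at 101 ± 6.65 CPM in GFP and 207 ± 37.9 CPM in SERPINA4 libraries, and the heat shock gene HSPA1B at 76.4 ± 0.514 and 105 ± 8.90 CPM (SD, n = 3 each). Neither TUBA1A nor HSPA1B passed the edgeR test (adjusted p = 0.267 and 0.211), though both did by DESeq2 (2.9e-11 and 0.0015), TUBA1A without SERPINA4 replicate 3 (0.00219) and HSPA1B without SERPINA4 replicate 1 (0.0385). Both were named after their values were seen.

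The tests on overlapping genes, on non-polyadenylated RNA and on the lists that lost their call were chosen after the results were seen. The tests of trends over all 9 lists, of the splits of the libraries and of the chromosome segment were written before theirs.

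The 8 called genes besides SERPINA4 were the first pattern. The tables argue against a shift of reads between overlapping genes for NFAT5, whose sum with the genes that overlap it had a log2 fold change of −1.35 (adjusted p = 0.0152), and for ADD3, CDC25B, MXI1, ZNF302, ZNF532 and ZNF652, where the overlapping genes, if any, held at most 1.47% of the difference between the groups in CPM. They also argue against the non-polyadenylated RNA of SERPINA4 replicate 2 alone for all 8 genes, which passed without that library. SERPINA4 replicate 3 came next in this RNA. Without it NFAT5, ADD3, ZNF302, ZNF532 and MRPL53 passed. MXI1, ZNF652 and CDC25B did not (edgeR adjusted p = 0.0577, 0.0615 and 0.0745). No fit left out both libraries, so carry-over in both is not excluded. For MRPL53 the sum had a log2 fold change of −0.30 and did not pass. That does not decide, because adding the counts of CCDC142 shrinks the fold whatever the cause. The sum was 29.9 ± 2.71 CPM in GFP and 24.2 ± 3.51 CPM in SERPINA4 libraries, and CCDC142 stood higher without passing. A shift of reads between MRPL53 and CCDC142 is thus a candidate for part or all of its fall, and was not settled. A lost chromosome segment in the SERPINA4 line may lower the neighbours ADD3 and MXI1, but the 10 genes beside them had a median log2 fold change of −0.024, with XPNPEP1 at 0.029 and SMNDC1 at 0.12, and with no tested gene between the pair a segment that ends inside these neighbours stays open, as does an effect of SERPINA4.

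The second pattern was the 9 lists that stood higher. After trends over mean expression, exonic length and GC content were each removed, 5, 7 and 8 of the 9 lists passed, ER included. These were camera calls at the preset correlation, and no list had passed with an estimated one. They argue against length and GC content as the whole cause. For mean expression the count does not decide. The rule asked for at least 5, and these included the histone list, treated below. The ER and respiratory chain medians were 0.113 and 0.093 before and 0.113 and 0.089 after, which argues against mean expression as their whole cause. The ribosomal protein and mitochondrially encoded lists went with mean expression. A second trend left out 45 genes, the mitochondrial ones and the ribosomal protein genes typed as protein-coding alone. With it, the lists kept 22.9% and 18.9% of their medians (0.060 to 0.014, and 0.096 to 0.018) on the voom scale, used for all trend tests. Neither passed, so a trend over abundance may account for the mitochondrially encoded list. Ribosomal protein genes with other transcript types stayed in the trend, so that list may have set part of it, and the test does not decide there. Calls ended with less change in the fold for the S phase and G2 and M phase lists under abundance (at least 72% of the median kept; G2 and M phase from 0.036, quartiles 0.023 and 0.080, to 0.026, quartiles 0.0064 and 0.066, adjusted p = 0.0622), the S phase and mitochondrially encoded lists under length (at least 78.8% kept; adjusted p = 0.0618 and 0.0643) and the immediate early list under GC content (63.4% kept; 0.14, quartiles −0.073 and 0.38, to 0.091, quartiles −0.084 and 0.38, adjusted p = 0.0678). The S phase median went from 0.048 to 0.046 under abundance (camera adjusted p = 0.0741) and to 0.055 under length. The lost calls of the S phase list therefore do not speak for either trend. For these lists the trends cannot be told apart from a change of the list itself, because most of the fold stayed while the p moved past 0.05. For the ER and respiratory chain lists an effect of SERPINA4, or of another difference between the lines, stays open.

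The third pattern was the histone list. SERPINA4 replicate 2 also held 49.1 CPM of RMRP and 64.1 CPM of RPPH1, against at most 0.966 and 3.92 CPM in the other libraries. Without it the list had a camera adjusted p of 0.230 and its median log2 fold change went from 0.92 to 0.19, so carry-over of non-polyadenylated RNA in that library may account for the rise. No biological explanation was tested.

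The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 9 genes, and 2 of the 10 splits, itself included, gave as many. The others gave 3, 16, 8, 6, 1, 7, 7, 7 and 3 genes, so counts near that of the real split were common. The 16 came where GFP replicates 1 and 2 were set with SERPINA4 replicate 2. For gene lists the real split gave 10, which it alone of the 10 splits reached, and the highest other gave 6.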
